A study of Homo sapiens with 9 samples.

How the data were processed

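Expression was measured in A673 cells, an established Ewing sarcoma cell line that carries the EWS/FLI1 gene fusion. Per the labels, 3 derivative lines were made, each with a doxycycline-inducible short hairpin RNA aimed at the 5′ untranslated region of the endogenous fusion transcript. The same cells carried an inducible construct for a flag tag alone, for 3xflag-EWS/FLI1, called the wild-type fusion here, or for its K380R form. Each line was profiled without doxycycline and after 24 h and 48 h at 0.1 ng/µl, which gave 9 arrays. The titles put the uninduced arrays at time point 48 h, so the 24 h induced arrays had no uninduced array of the same time point. Total RNA was amplified, labelled with biotin and hybridised to single-channel arrays, per the labels' protocols.

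The deposited values are log2 expression levels per probe set, which the authors made with RMA, per the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays together and summarises the probes of a probe set on the log2 scale. It compresses changes of dim probe sets and makes the overall distributions of the arrays alike, so a shift of all genes together cannot be seen. The RMA version and the genome build were not given in the sources used here, and no coordinates are printed. The table held 53617 probe sets. Array medians lay between 4.44 and 4.50. No columns were pooled and no scan dates or batches were used here.

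The platform annotation used here gave 1 gene symbol for 16098 probe sets and several for 0, and 37519 were unnamed here. All 16098 gene identifiers matched the RefSeq gene table of GRCh38.p14, which changed 0 symbols. Where a gene had several probe sets (779 genes), the one with the highest mean over all arrays was used, which left 14884 genes. No named probe set was held for NR0B1, PRKCB, TGFBR2 or CAV1, which were not analysed here.

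Groups were taken from the sample titles, with 3 uninduced arrays (1 per line) and 2 induced arrays (24 h and 48 h) for each of the tag-only, wild-type and K380R lines. For the K380R line, the source-name label exchanges the uninduced and the 24 h arrays against the title and the description. The titles were followed, and the exchange was run as an alternative. Every condition had 1 array. The labels do not say that arrays came from separate cultures, so p-values measure the spread among the uninduced arrays of 3 lines and the departure of the induced arrays from a time shift shared by the lines, and part of that spread may be technical.

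Comparisons used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with all 9 arrays in 1 model of 4 groups and a time term coded -0.5 for 24 h, 0.5 for 48 h and 0 for uninduced. The model had 4 residual degrees of freedom, to which eBayes added 3.32. The 6 induced arrays were also compared with the 3 uninduced ones in a model of 2 groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Errors are standard errors (SE) of the log2 difference from the model. The number of arrays limits the precision, with a median SE of 0.11 to 0.13 in the comparisons between groups.

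A line's own change is the mean of its induced arrays minus its own uninduced array. The degree to which re-expression reversed the tag-only line's changes was summarised as a slope through the origin of a re-expressing line's own change on the tag-only line's own change, over genes with a change of 1 or more on the log2 scale, in the same direction, at both times in the tag-only line. A slope of 1 means no reversal. A slope near 0 means reversal only if the tag-only change is real, since genes chosen through noise in the single uninduced array would give it too. The genes were therefore also chosen on 1 tag-only array against the uninduced array of a line outside the slope. Their changes were then measured on the other tag-only array against its own uninduced array, as a ratio of mean changes. The slope carries no p, since genes are not replicates, and the changes of 2 lines share no array.

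Before the data were examined, 21 gene lists were fixed from general knowledge, and the 20 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. They held genes known to be activated or repressed by EWS/FLI1, G1/S replication genes, G2/M genes, p53 targets, extracellular matrix genes, actin and adhesion genes, YAP/TEAD targets, TGF-beta response genes, interferon response genes, NF-kappa-B targets and cytokines, cholesterol synthesis, glycolysis and hypoxia, ATF4 and unfolded protein response, ribosome biogenesis, nuclear-encoded oxidative phosphorylation, neural, mesenchymal, ubiquitin and proteasome, leukocyte and epithelial genes. Camera with an estimated correlation and fry were run beside it. The genes named below follow a rule fixed at the same point. They are FLI1, EWSR1 and 10 well-known fusion targets, the 10 largest rises and 10 largest falls of each comparison among called genes whose arrays lay outside the range of the reference arrays, and the called members of each list (or otherwise the 4 members with the largest change). Genes that fall outside this rule are said to have been chosen after their values were seen.

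The analysis was tested on simulated data built on the real genes. In the comparison of tag-only with uninduced arrays, 31.3% of changes of 0.5, 98.5% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered, and 6.13% of calls were false. Over the simulated comparisons 5.10% to 7.79% of calls were false, and up to 12.8% with the own-line reference. The simulated arrays shared 1 starting mean per gene and had independent noise. They held no differences between lines and no dependence between the arrays of a line. Both can add false calls in the real data, so these shares may be too low. Of unchanged lists, 7% were called at the preset correlation. The genes of these simulated lists varied independently, whereas the estimated correlation of real lists reached 0.66 (G1/S genes, induced against uninduced arrays). The 7% is therefore not the false share of the list calls given below. Alternatives were an added 2-fold threshold, no time term, each line's own uninduced array as its reference, either time alone, the exchanged labels, removal of dim genes, means over probe sets, cyclic loess normalization, a trended robust variance model and leaving out each array in turn. Testing all probe sets, leaving microRNA genes out of the slopes and choosing their genes on other arrays were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.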

Results

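Gene expression was profiled on 9 arrays of A673 Ewing sarcoma cells. Per the labels, doxycycline induces a hairpin against endogenous EWS/FLI1 in these cells together with a flag tag, the tagged wild-type fusion or its K380R form. The fusion joins part of EWSR1 to the DNA-binding part of the transcription factor FLI1, and K380R replaces a lysine of the protein by arginine. The design addresses which genes depend on the level of the fusion protein. The groups were 3 uninduced arrays, 1 per line, and 2 arrays (24 h and 48 h of doxycycline) each for the tag-only, wild-type and K380R lines. Between pairs of uninduced arrays, 53 to 64 of 14884 genes differed at least 2-fold.

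No difference in the transcripts of the fusion partners passed the test. The FLI1 probe set lay at 5.45 ± 0.05 (SD, n = 3) on the log2 scale in uninduced cells, 5.35 ± 0.18 (SD, n = 2) in the tag-only line, 5.53 ± 0.07 (SD, n = 2) in the wild-type line and 5.48 ± 0.12 (SD, n = 2) in the K380R line. Its range over the 9 arrays was 5.23 to 5.58. FLI1 differed by -0.09 ± 0.08 (SE) between tag-only and uninduced arrays (limma adjusted p = 0.73) and by 0.08 ± 0.08 between wild-type and uninduced arrays (adjusted p = 0.61). EWSR1, whose first part is shared with the fusion, lay at 8.11 ± 0.10 (SD, n = 3) in uninduced and 7.99 ± 0.04 (SD, n = 2) in tag-only cells, a difference of -0.12 ± 0.09 (SE, adjusted p = 0.71). Where the probes of these probe sets lie in the transcripts is not given in the sources used here, so they check neither the silencing nor the re-expression.

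The induced tag-only arrays were compared with the uninduced arrays, a contrast that holds doxycycline and the hairpin along with any silencing of the fusion. DKK1, a secreted Wnt antagonist, was higher by 2.50 ± 0.28 (log2, SE; 2 tag-only against 3 uninduced arrays, adjusted p = 0.021). PCDH18, a protocadherin, rose by 1.76 ± 0.23, and SPP1, which encodes osteopontin, by 1.65 ± 0.16. SNAI2, the mesenchymal transcription factor Slug, rose by 1.52 ± 0.14 and TOX by 1.50 ± 0.14. IGFBP5 (1.46) and IGFBP7 (1.26), which encode insulin-like growth factor binding proteins, GPR37 (1.29), LRRC17 (1.13) and the lymphangiogenic growth factor VEGFC (1.12) also rose. The complement gene C7 fell by 1.94 ± 0.20, and CXCR4, the receptor for CXCL12, fell by 1.92 ± 0.29. GPR174 (-1.74), the tetraspanin gene TSPAN8 (-1.70), CEACAM6 (-1.52), FEZF1-AS1 (-1.48), CLUL1 (-1.44), BASP1-AS1 (-1.26), GADL1 (-1.22) and MIMT1 (-1.21) were the other largest falls. CEACAM6 has close relatives whose transcripts its probes may also bind, so its value is uncertain. Some of these genes, such as CXCR4, C7 and SPP1, changed as much where a fusion was re-expressed, as given below.

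Of 25 measured genes known to be activated by EWS/FLI1, 5 fell, 0 rose and 20 did not pass the test, with 14 lower when adjusted over the list alone. STEAP1 fell by 1.17 ± 0.15 and the homeobox gene NKX2-2 by 0.95 ± 0.12, and DKK2 (-0.91), SOX2 (-0.91) and FEZF1 (-0.77) also fell. A second NKX2-2 probe set differed by -0.18. The list's median was -0.39 (camera adjusted p = 1.5e-13), and this call held with an estimated correlation (adjusted p = 0.020). Of 18 measured genes known to be repressed by the fusion, 4 rose (DKK1, IGFBP5, IGFBP7 and the hyaluronan receptor gene CD44, by 0.93), with 8 when adjusted over the list alone. The list's median was 0.34 (adjusted p = 3.7e-08; adjusted p = 0.22 with an estimated correlation). Among other known targets, LOX differed by 1.11 ± 0.20 (adjusted p = 0.059), CCND1 by -0.39 (adjusted p = 0.16). IGFBP3 differed by -0.24 (adjusted p = 0.61) and FOXO1 by 0.26 (adjusted p = 0.50). None of these 4 genes passed the test.

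Other lists moved less. G1/S replication genes had a median of -0.20 with 0 of 22 called (adjusted p = 2.7e-06; adjusted p = 0.22 with an estimated correlation). MCM3 stood at -0.42, and over all genes 1744 had an unadjusted p under 0.05. Cholesterol synthesis genes had a median of -0.25 with 0 of 16 called (adjusted p = 2.7e-06; adjusted p = 0.22 with an estimated correlation), and INSIG1 stood at -0.72. ATF4 and unfolded protein response genes had a median of -0.23 (adjusted p = 0.0012; adjusted p = 0.55 with an estimated correlation). Actin and adhesion genes had a median of 0.20 with 1 of 15 called, TPM1 at 0.65 (adjusted p = 0.00014; adjusted p = 0.22 with an estimated correlation). Extracellular matrix genes had a median of 0.22 with 1 of 13 called, the lysyl oxidase LOXL2 at 0.57 (adjusted p = 0.0063; adjusted p = 0.29 with an estimated correlation). Mesenchymal genes had a median of 0.12 with SPP1 and SNAI2 called among 17 (adjusted p = 0.0038; adjusted p = 0.22 with an estimated correlation). YAP/TEAD targets had a median of 0.09 with DOCK5 called at 0.63 (adjusted p = 0.0093; adjusted p = 0.40 with an estimated correlation). G2/M genes had a median of -0.08 (adjusted p = 0.042; adjusted p = 0.56 with an estimated correlation). Ribosome biogenesis genes had a median of -0.07 (adjusted p = 0.041; adjusted p = 0.22 with an estimated correlation). MYC, on the ribosome biogenesis list, fell by 0.78. The lists of p53 targets (adjusted p = 0.31), TGF-beta response (0.37), interferon response (0.35), NF-kappa-B (0.22) and glycolysis and hypoxia genes (0.90) were not called. The TGF-beta list had a median of -0.04 and a mean of 0.13. Oxidative phosphorylation (adjusted p = 0.35), neural (0.48), leukocyte (0.95) and epithelial genes (0.31) were not called as lists either. B2M on the interferon list fell by 0.53 (-0.24 at a second probe set), and the receptor tyrosine kinase gene RET on the neural list fell by 1.07. Of the ubiquitin and proteasome list only 4 genes were measured, and it was not tested.

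In all, 136 genes were called between tag-only and uninduced arrays, 59 higher and 77 lower, of which 36 changed at least 2-fold. Against its own uninduced array, the tag-only line had 38 genes at least 2-fold higher and 58 lower at 24 h, and 69 and 50 at 48 h. The SD of these changes over all genes was 0.26 and 0.28, little above the 0.24 to 0.26 between pairs of uninduced arrays. With each line's own uninduced array as reference limma called 0 genes (1278 at an unadjusted p under 0.05), and it also called 0 with either time alone, with all probe sets tested and with the exchanged K380R labels (1629 genes at 24 h, 1781 at 48 h, 4264 probe sets and 1249 genes at an unadjusted p under 0.05). The own-line reference also ended the calls of the extracellular matrix (adjusted p = 0.090), G2/M (0.14) and ribosome biogenesis (0.11) lists. Leaving out 1 array left 0 calls (the uninduced array of the tag-only line, either tag-only array or either K380R induced array), 1 call (the uninduced array of the K380R line or either wild-type induced array) or 29 calls (the uninduced array of the wild-type line).

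**Figure D1:**
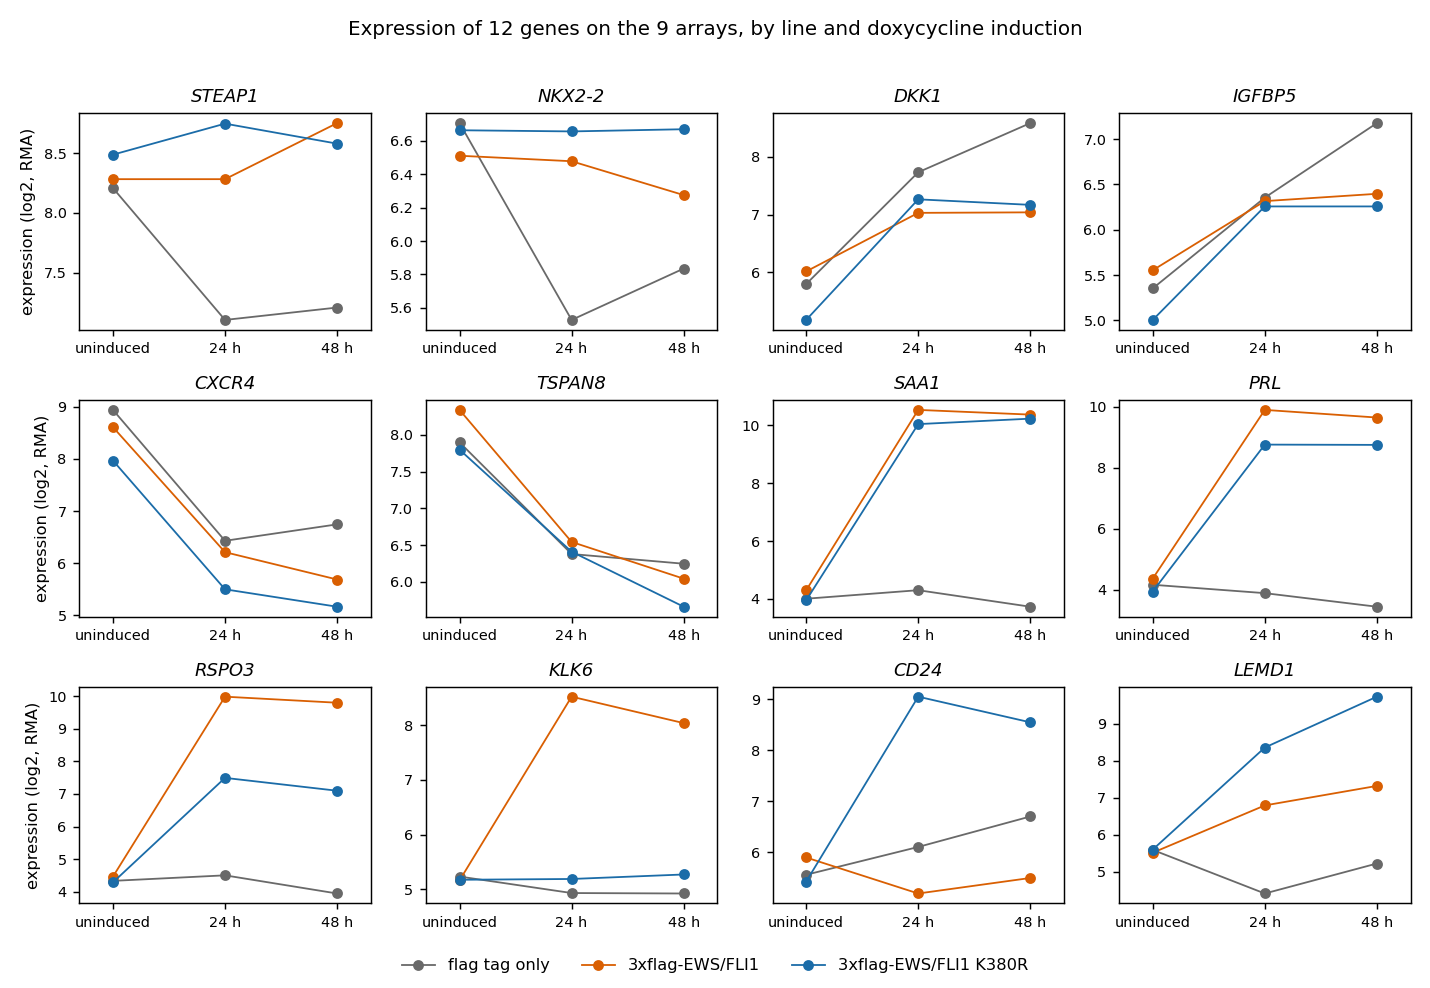
Log2 expression (RMA, vertical axes, each with its own range) of 12 genes on the 9 arrays, with induction on the horizontal axes and 1 point per array joined by line. STEAP1 and NKX2-2 fell in the tag-only line, CXCR4 and TSPAN8 were lower on all 6 induced arrays, SAA1 and PRL were higher in both re-expressing lines, KLK6 was higher in the wild-type line and CD24 was highest in the K380R line.

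The line with the wild-type fusion was compared with the tag-only line at the same doxycycline exposure (2 arrays each). The largest rises were those of SAA1, an acute-phase protein gene, by 6.43 ± 0.19 (log2, SE; limma adjusted p = 8.4e-06), of PRL, which encodes prolactin, by 6.11 ± 0.16, and of RSPO3, an enhancer of Wnt signalling, by 5.67 ± 0.12. EFNB2 (ephrin-B2, 4.73), the peptidase gene DPP4 (4.63), ULBP1 (4.41), KMO, an enzyme of tryptophan breakdown (4.36), KDM7A-DT (4.27), the cancer-testis gene FATE1 (4.23) and the transcription factor gene EBF2 (4.18) followed. SAA1 has a near-identical relative whose transcript its probes may also bind, so its value is uncertain. With the tag alone SAA1 (4.02), PRL (3.67), RSPO3 (4.22) and EFNB2 (3.02) lay below the arrays' medians, EFNB2 within the range of the arrays' lower quartiles (3.01 to 3.07). Such levels may be background, so these rises are lower bounds and their order is uncertain. ASS1, which encodes argininosuccinate synthase, fell by 2.27 ± 0.40, and ODAD2 (-1.79), LRRC15 (-1.70), the angiopoietin gene ANGPT1 (-1.67), HEBP2 (-1.65), LOC730101 (-1.65), TMT1A (-1.61), C5orf63 (-1.55), GM2A (-1.55) and MIR1587 (-1.54) were the other largest falls. The second MIR1587 probe set differed by 0.10. With the wild-type fusion TMT1A, C5orf63 and MIR1587 lay below the arrays' medians, and the sizes of their falls are uncertain.

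Of the 25 genes known to be activated by the fusion, 11 rose, 2 fell and 12 did not pass the test against the tag alone, with 12 higher and 3 lower when adjusted over the list alone (median 0.21, adjusted p = 0.0013; adjusted p = 0.24 with an estimated correlation). PAX7 (1.75), GSTM4 (1.75), STEAP1 (1.36), FEZF1 (1.16) and NKX2-2 (0.70; 0.16 at its second probe set) rose, and ADGRG2 (-0.77) and HOXD13 (-0.45) fell. Of 18 genes known to be repressed by it, 3 rose (LTBP1 by 1.49, JAG1 by 0.71, TIMP1 by 0.58) and 3 fell (LOX by -0.85, CD44 by -0.71, MME by -0.69), and the list was not called (median -0.22, adjusted p = 0.70). CCND1 (-0.31), IGFBP3 (0.53) and FOXO1 (-0.21) did not pass the test. G1/S replication genes were lower than with the tag alone, with 14 of 22 called lower, 0 higher and a median of -0.50 (adjusted p = 7.9e-09; adjusted p = 0.24 with an estimated correlation). They included GINS2 (-0.97), UHRF1 (-0.82), MCM7 (-0.73) and CDC45 (-0.73), which act in DNA replication or its control. Of 23 G2/M genes, 3 were called lower (CDC20 by -0.62, NDC80 by -0.47, KIF11 by -0.41), with a median of -0.39 (adjusted p = 0.00010; adjusted p = 0.75 with an estimated correlation).

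Actin and adhesion genes were lower by a median of -0.24, with CALD1 (-0.72), VCL (-0.65), TPM1 (-0.53) and TAGLN2 (-0.40) called among 15 (adjusted p = 0.0081; adjusted p = 0.51 with an estimated correlation). Extracellular matrix genes were lower by a median of -0.16, with BGN (-1.23), LOXL2 (-0.98), LOX and FSTL1 (-0.62) called lower (adjusted p = 0.023; adjusted p = 0.57 with an estimated correlation). LUM was called higher too, but at 2.75 and 3.20 it lay near or below the arrays' lower quartiles in both lines, so no rise is shown. Cholesterol synthesis genes had a median of -0.24, with PMVK (-0.69) and ACAT2 (-0.53) called (adjusted p = 0.025; adjusted p = 0.81 with an estimated correlation). ATF4 and unfolded protein response genes had a median of 0.30, with STC2 (1.79) called (adjusted p = 0.023; adjusted p = 0.87 with an estimated correlation). On lists that were not called, LPL, which encodes lipoprotein lipase (3.55), PTGS2, which encodes cyclooxygenase-2 (1.91), BAMBI (1.53), THY1 (1.11), MYC (0.90) and NCAM1 (0.82) rose. On such lists AXL (-1.08), SNAI2 (-0.99), CHGB (-0.99), OCLN (-0.99) and GAP43 (-0.93) fell. LPL (3.46 with the tag alone) and CHGB (4.08 with the wild-type fusion) lay below the arrays' medians there, so the rise of LPL is a lower bound and the size of the fall of CHGB is uncertain.

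The wild-type line differed from the tag-only line in 1658 genes, 802 higher and 856 lower. The balance depended on the processing, with 895 higher and 646 lower after cyclic loess and 1038 higher and 569 lower over all probe sets. Of the 429 that differed at least 2-fold, 318 were higher and 111 lower. As differences between each line's own changes the count was 63 (61 higher, 2 lower), and the extracellular matrix (adjusted p = 0.091), cholesterol synthesis (0.21) and ATF4 (0.80) lists were not called. At 24 h alone limma called 0 genes (2771 at an unadjusted p under 0.05), at 48 h alone 28 and with the exchanged K380R labels 333. It was 763 without the tag-only 24 h array, 444 without the tag-only 48 h array, 850 without the wild-type 24 h array and 482 without the wild-type 48 h array.

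In the line with the K380R form, compared with the tag-only line in the same way, SAA1 was higher by 6.12 ± 0.19 (log2, SE; 2 arrays each, limma adjusted p = 2.5e-05) and PRL by 5.09 ± 0.16. The cancer-testis gene LEMD1 (4.22), DPP4 (3.89), KMO (3.58), MAP7D2 (3.51), KDM7A-DT (3.42), the growth factor gene IGF1 (3.26), CLIC5 (3.19) and APOH (3.14) were the next largest rises. With the tag alone SAA1, PRL, CLIC5 and APOH lay below the arrays' medians, so their rises are lower bounds and their order is uncertain. TOX fell by 1.97 ± 0.16, and ASS1 (-1.81), MET, which encodes the hepatocyte growth factor receptor (-1.76), UST (-1.73), ANGPT1 (-1.72), TMSB15A (-1.57), TMTC1 (-1.57), LRRC15 (-1.56), LOC730101 (-1.53) and DPYD (-1.51) also fell.

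Of the 25 genes known to be activated by the fusion, 8 rose, 0 fell and 17 did not pass the test, with 12 higher and 1 lower when adjusted over the list alone (median 0.30, adjusted p = 1.1e-05; adjusted p = 0.10 with an estimated correlation). GSTM4 (1.84), STEAP1 (1.51), PAX7 (1.42), SOX2 (1.01) and NKX2-2 (0.98; 0.38 at its second probe set) were among them. Of the 18 repressed genes, IGFBP7 (-1.29), IER3 (-1.05; other probe sets -0.55 to -1.05), CD44 (-0.88) and MME (-0.53) fell and TIMP1 (0.72) rose, with a median of -0.31 (adjusted p = 0.036; adjusted p = 0.65 with an estimated correlation). LOX (-0.75), CCND1 (0.13), IGFBP3 (0.47) and FOXO1 (-0.05) did not pass the test. Of the G1/S replication genes only CDC45 was called (-0.47), with a median of -0.21 (adjusted p = 0.0012; adjusted p = 0.48 with an estimated correlation). Extracellular matrix genes were lower by a median of -0.36, with FBN1 (-0.97), BGN (-0.74) and LOXL2 (-0.69) called (adjusted p = 0.0015; adjusted p = 0.48 with an estimated correlation). YAP/TEAD targets had a median of -0.24, with AXL (-1.35), DOCK5 (-1.13) and MYOF (-0.74) called (adjusted p = 0.022; adjusted p = 0.53 with an estimated correlation). Actin and adhesion genes had a median of -0.15, with CALD1 (-0.66), TPM1 (-0.62; -0.96 at a second probe set) and VCL (-0.59) called (adjusted p = 0.036; adjusted p = 0.53 with an estimated correlation).

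The K380R line differed from the tag-only line in 791 genes, 429 higher and 362 lower. The balance depended on the processing, with 469 higher and 321 lower after cyclic loess and 479 higher and 223 lower over all probe sets. Of the 253 that differed at least 2-fold, 188 were higher and 65 lower. The count was 4 as differences between each line's own changes, where the repressed (adjusted p = 0.42), G1/S (0.13), extracellular matrix (0.13), YAP/TEAD (0.42) and actin (0.060) lists were not called. Limma called 0 genes at 24 h alone, at 48 h alone and with the exchanged labels (2116, 2570 and 1714 at an unadjusted p under 0.05). It was 345 without the tag-only 24 h array, 136 without the tag-only 48 h array, 179 without the K380R 24 h array and 103 without the K380R 48 h array.

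The K380R form was then set against the wild-type fusion (2 arrays each). CD24, which encodes a small surface glycoprotein, was higher with K380R by 3.46 ± 0.26 (log2, SE; limma adjusted p = 0.0043), LEMD1 by 1.99 ± 0.18 and IGF1 by 1.49 ± 0.25. GRP, which encodes gastrin-releasing peptide (1.32), GBP4 (1.31), LSP1P3 (1.29), TMT1A (1.26), LINC01085 (1.20), PDGFD (1.16) and the tight-junction gene OCLN (1.13) were also higher. KLK6, a kallikrein protease gene, was lower with K380R by -3.05 ± 0.14 (adjusted p = 0.00047), the adhesion gene CADM1 by -2.83 ± 0.16, the interferon-induced ligase gene HERC5 by -2.68 ± 0.24 and HS3ST2 by -2.68 ± 0.31. RSPO3 (-2.60), EFNB2 (-2.56), the complement gene C3 (-2.55), RGS1 (-2.28), the anti-apoptotic gene BCL2A1 (-2.20) and TTPA (-2.14) were lower too. A second CADM1 probe set differed by -1.05. CD24 has near-identical copies elsewhere in the genome, so its value is uncertain. GBP4, LSP1P3, TMT1A, HERC5, RGS1 and TTPA lay below the arrays' medians in the line with the lower level, so the sizes of their differences are uncertain.

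No gene on the list of fusion-activated genes was called between the 2 forms (0 of 25, median 0.03, adjusted p = 0.64). Over all genes limma gave 2305 an unadjusted p under 0.05. STEAP1 differed by 0.15 ± 0.16 (SE), NKX2-2 by 0.29 ± 0.14 and CCND1 by 0.43 ± 0.11 (adjusted p = 0.12). LOX (0.11), IGFBP3 (-0.06) and FOXO1 (0.16) did not pass the test. Of the repressed genes LTBP1 was lower with K380R (-1.69), and the list was not called (adjusted p = 0.084). G1/S replication genes lay above the wild-type line by a median of 0.32 with 20 of 22 above 0 and 0 called (adjusted p = 5.6e-07; adjusted p = 0.42 with an estimated correlation). Adjusted over the list alone, 10 were higher and 1 lower. G2/M genes lay above it by a median of 0.23 with 23 of 23 above 0 and 0 called (adjusted p = 7.2e-05; adjusted p = 0.49 with an estimated correlation). Cholesterol synthesis genes had a median of 0.28, with PMVK called at 0.64 (adjusted p = 0.00080; adjusted p = 0.48 with an estimated correlation). NF-kappa-B targets and cytokines had a median of -0.20, with PTGS2 called at -1.81 (adjusted p = 0.012; adjusted p = 0.42 with an estimated correlation). Mesenchymal genes had a median of -0.16, with LPL called at -2.04 (adjusted p = 0.012; adjusted p = 0.42 with an estimated correlation). NCAM1, a neural adhesion gene, was lower by -1.26.

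The 2 forms differed in 144 genes, 39 higher and 105 lower with K380R. Of the 73 that differed at least 2-fold, 13 were higher and 60 lower. As differences between each line's own changes limma called 0 genes (1227 at an unadjusted p under 0.05), and the G2/M (adjusted p = 0.15), cholesterol synthesis (0.36), NF-kappa-B (0.83) and mesenchymal (0.33) lists were not called. It also called 0 at 24 h alone and at 48 h alone (1752 and 2057 at an unadjusted p under 0.05), while the exchanged labels gave 27, testing all probe sets 15, dropping dim genes 254 and the trended robust model 312. The count was 83 without the uninduced array of the tag-only line, 87 without either tag-only induced array, 18 and 6 without the wild-type 24 h and 48 h arrays, and 13 and 9 without the K380R 24 h and 48 h arrays.

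The own changes of the 2 re-expressing lines were compared directly, since they share no array. Over all 14884 genes they correlated at r = 0.58 (Spearman's rho = 0.38), whereas the tag-only line's own change correlated with that of the wild-type line at r = 0.03 (rho = 0.04) and with that of the K380R line at r = 0.06 (rho = 0.07). These 3 correlations are across genes, which are not independent replicates. SAA1 rose by 6.15 in the wild-type and 6.18 in the K380R line, PRL by 5.41 and 4.81, and RSPO3 by 5.43 and 3.01, from dim starting levels. KLK6 stood at 3.12 and 0.06, and CD24 at -0.55 and 3.38.

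**Figure D2:**
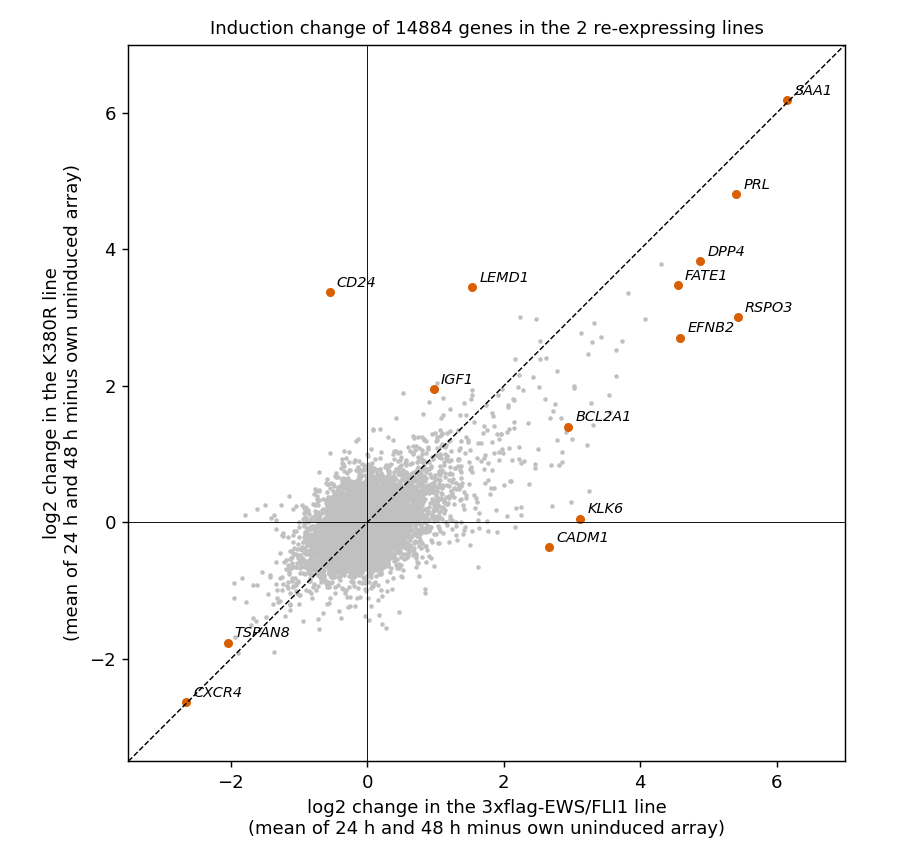
Own change of each of 14884 genes (grey points, mean of 24 h and 48 h minus the line's own uninduced array, log2) in the 3xflag-EWS/FLI1 line (horizontal axis) and the K380R line (vertical axis), with named genes in orange and a dashed line of equal change. SAA1 lay near the line at 6.15 and 6.18, RSPO3, KLK6 and CADM1 lay below it, and CD24 and LEMD1 above it.

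Against the uninduced arrays, the wild-type line differed in 1661 genes, 774 higher and 887 lower. The balance turned to 906 higher and 734 lower after cyclic loess and 999 higher and 717 lower over all probe sets, and at least 2-fold it was 288 higher and 84 lower. The K380R line differed in 544, 297 higher and 247 lower, with 332 and 226 after cyclic loess, 253 and 110 over all probe sets and 132 and 39 at least 2-fold. In the wild-type line SAA1 (6.37 ± 0.17, log2, SE), PRL (5.61), RSPO3 (5.53), EFNB2 (4.78), DPP4 (4.67), FATE1 (4.47), LINC00707 (4.45), MXRA5 (4.06), KDM7A-DT (3.94) and HS3ST2 (3.86) rose. CXCR4 (-2.56), TMT1A (-2.13), the pituitary transcription factor gene POU1F1 (-1.94), C7 (-1.86), MMD (-1.82), CCDC102B (-1.74), PRRG4 (-1.72), TSPAN8 (-1.72), C5orf63 (-1.70) and TMSB15A (-1.67) fell. In the K380R line SAA1 (6.05), PRL (4.60), DPP4 (3.92), LEMD1 (3.47), LINC00707 (3.35), FATE1 (3.25), MXRA5 (3.25), CD24 (3.17), CLIC5 (3.13) and KDM7A-DT (3.10) rose. In the same line CXCR4 (-3.17), TSPAN8 (-1.98), TMSB15A (-1.95), C7 (-1.94), ADGRG2 (-1.51), POU1F1 (-1.50), RGS1 (-1.48), TLL1 (-1.44), NPR3 (-1.43) and DPYSL5 (-1.40) fell. In the uninduced arrays SAA1, PRL, RSPO3, EFNB2, HS3ST2 and CLIC5 lay below the arrays' medians, as did TMT1A and C5orf63 in the wild-type line and RGS1 in the K380R line, so the sizes of their changes are uncertain. STEAP1 (0.19 and 0.34) and NKX2-2 (-0.25 and 0.04) did not pass the test in either line. CCND1, which encodes cyclin D1, fell in the wild-type line by 0.70 (limma adjusted p = 0.0060) and stood at -0.27 in the K380R line (adjusted p = 0.23). With each line's own uninduced array as reference the counts were 296 and 48, at 24 h alone 0 and 0 (3038 and 1937 at an unadjusted p under 0.05), at 48 h alone 39 and 0, and with the exchanged labels 62 and 0. For the wild-type line the count was 710 and 434 without its 24 h and 48 h arrays and 1007 without the uninduced array of the tag-only line. For the K380R line it was 93 and 51 without its 24 h and 48 h arrays, and 213 and 334 without the uninduced arrays of the tag-only and wild-type lines.

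Whether re-expression returned the tag-only line's changes to their starting level was followed over the 35 genes that changed at least 2-fold at both times in the tag-only line, 20 lowered and 15 raised. The slope of the wild-type line's own change on that of the tag-only line was 0.17 (0.15 at 24 h and 0.18 at 48 h), and that of the K380R line was 0.19 (0.16 at 24 h and 0.23 at 48 h). Over the lowered genes the slopes were 0.067 and 0.11 and over the raised genes 0.30 and 0.30. Both sets held microRNA genes. Leaving these out left 27 genes in all, with slopes of 0.19 in the wild-type line and 0.24 in the K380R line. Among the lowered genes, ones that overshot their starting level offset ones that were not reversed. STEAP1 stood at -1.05 in the tag-only line, 0.23 in the wild-type line and 0.18 in the K380R line, and GPR174 at -1.61, 0.01 and -0.15. In contrast CXCR4 stood at -2.35, -2.66 and -2.64, C7 at -1.94, -1.90 and -1.91, TSPAN8 at -1.59, -2.05 and -1.76, RET at -1.35, -1.02 and -0.86, and SPP1 at 1.49, 1.33 and 1.35. Of the 20 lowered genes, 8 kept 0.5 or more of the tag-only change in the same direction in the wild-type line and 8 in the K380R line, while 6 and 4 moved by 0.5 or more of it in the opposite direction. Of the 15 raised genes, 5 and 5 kept 0.5 or more of the change, and 0 and 2 moved as far in the opposite direction. The slopes summarise genes that went both ways, and these have no replicate check. Genes chosen on other arrays, at 24 h or 48 h, changed by a mean of 0.61 or 0.50 in the tag-only line and 0.047 or 0.077 in the wild-type line, a pooled ratio of 0.12. For the K380R line the means were 0.47 or 0.43 against 0.033 or 0.11, a ratio of 0.18. The tag-only changes of such genes were thus smaller than the 2-fold that the main choice asks for. Without the tag-only 24 h array the slopes were 0.050 and 0.098, and without its 48 h array 0.069 and 0.085. They were 0.38 and 0.33 with the mean of the 3 uninduced arrays as reference and 0.26 and 0.45 over the fixed lists of fusion targets. They were 1.13 and 1.12 over the 1 gene that changed by 2 or more (CXCR4), and -0.073 for K380R with the exchanged labels.

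**Figure D3:**
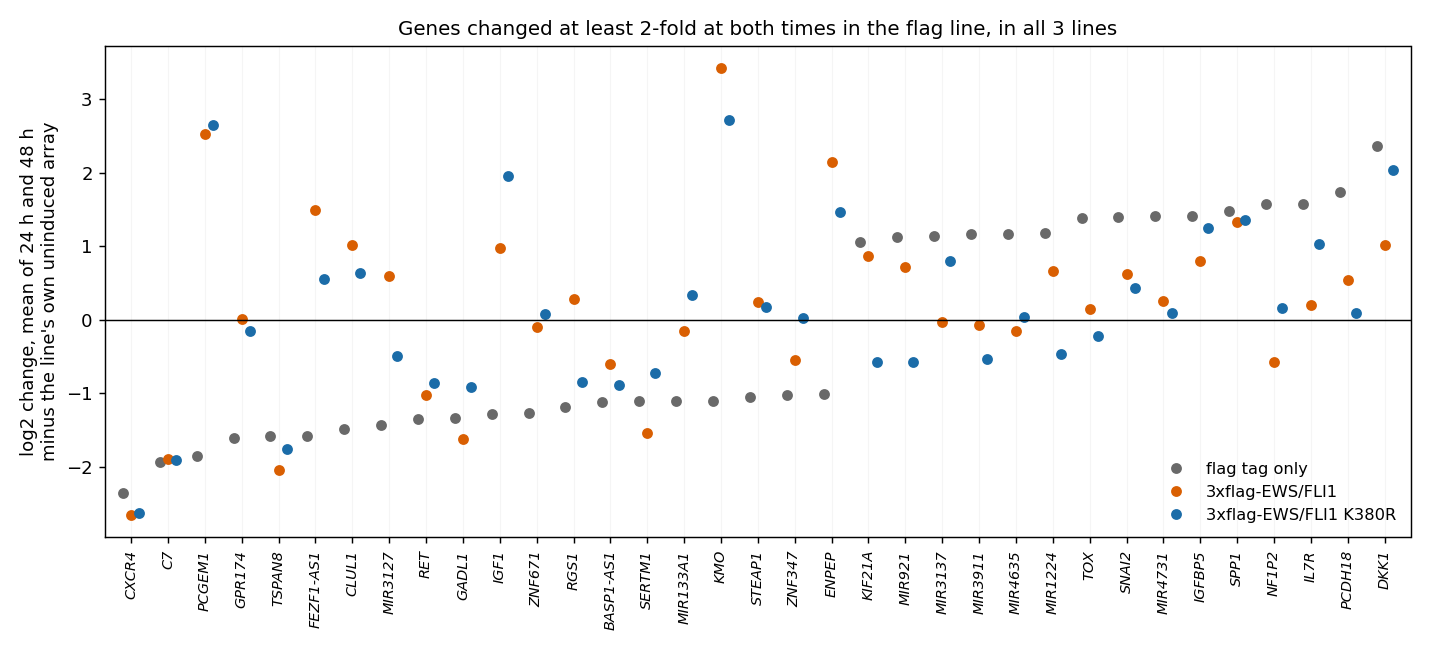
Own change (log2, mean of 24 h and 48 h minus the line's own uninduced array, vertical axis) of the 35 genes that changed at least 2-fold at both times in the tag-only line, ordered by that line's change along the horizontal axis, with 1 point per line. CXCR4, C7, TSPAN8 and SPP1 changed alike in all 3 lines, STEAP1 lay near 0 in both re-expressing lines, and PCGEM1 and KMO lay above 2 there.

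Induction of any construct was compared with no induction over 6 induced and 3 uninduced arrays. SPP1 rose by 1.39 ± 0.18 (log2, SE; limma adjusted p = 0.028) and GBP3, an interferon-inducible GTPase gene, by 1.05 ± 0.12. CXCR4 (-2.55 ± 0.35), C7 (-1.91), TSPAN8 (-1.80), ANKRD26P3 (-1.33), GADL1 (-1.29), SYTL5 (-1.09), RET (-1.08), the lymphoid transcription factor gene IKZF2 (-1.05), the Wnt pathway gene DKK2 (-0.98) and MYEOV (-0.88) fell. All 22 G1/S replication genes lay below 0, with 16 lower when adjusted over the list alone and 0 over all genes. Their median was -0.48 (adjusted p = 1.6e-12; adjusted p = 0.25 with an estimated correlation). All 16 cholesterol synthesis genes lay below 0, with 5 lower when adjusted over the list alone and 0 over all genes. Their median was -0.33 (adjusted p = 5.9e-09; adjusted p = 0.25 with an estimated correlation). All 23 G2/M genes lay below 0, with a median of -0.24 and 0 called (adjusted p = 1.4e-06; adjusted p = 0.44 with an estimated correlation). Genes known to be repressed by the fusion had a median of 0.38, with DKK1 at 1.81 and IGFBP5 at 1.16 short of the threshold for single genes (list adjusted p = 1.6e-06; adjusted p = 0.25 with an estimated correlation). Genes known to be activated by the fusion had a median of -0.08, with DKK2 called, 16 of 25 below 0 and 6 lower when adjusted over the list alone (adjusted p = 0.0073; adjusted p = 0.25 with an estimated correlation). Mesenchymal genes had a median of 0.09, with SPP1 called (adjusted p = 0.0031; adjusted p = 0.25 with an estimated correlation). ATF4 and unfolded protein response genes had a median of -0.20 with 0 called (adjusted p = 0.044; adjusted p = 0.69 with an estimated correlation and 0.12 with the own-line reference). In all 15 genes were called, 2 higher and 13 lower (1405 at an unadjusted p under 0.05). The count was 51, all 15 among them, with each line's own uninduced array as reference, 0 at 24 h alone, 2 at 48 h alone, 0 with the exchanged labels and 2 with all probe sets tested. It was 1, 1 and 2 without the uninduced array of the tag-only, wild-type and K380R line.

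Between 24 h and 48 h of induction, MIR21, a microRNA gene, rose by 1.98 ± 0.14 (log2, SE; 3 lines, limma adjusted p = 0.020) and LRRC17 by 1.23 ± 0.10 (adjusted p = 0.026), in the same direction in all 3 lines. MIR21 at 24 h lay below its own uninduced level in each line (4.94 against 5.51 in the tag-only, 4.12 against 5.45 in the wild-type and 4.40 against 5.41 in the K380R line), so its rise includes a dip at 24 h. The uninduced arrays are titled time point 48 h. Induction and culture time therefore cannot be told apart for this dip or for any shift between 24 h and 48 h given here. The 24 h values of the wild-type and K380R lines also lay below the arrays' medians, so the size of the rise is uncertain. These were the only 2 genes called, with 1673 at an unadjusted p under 0.05. Extracellular matrix genes were higher at 48 h by a median of 0.25 with 0 of 13 called, and LOX stood at 0.93 and FBN1 at 0.83 (adjusted p = 5.6e-06; adjusted p = 0.18 with an estimated correlation). Mesenchymal genes had a median of 0.15 (adjusted p = 0.00028; adjusted p = 0.18 with an estimated correlation). Ribosome biogenesis genes had a median of -0.13 with NOP16 at -0.37 (adjusted p = 0.00036; adjusted p = 0.18 with an estimated correlation). Repressed targets of the fusion had a median of 0.13 (adjusted p = 0.00075) and G1/S replication genes one of -0.11 (adjusted p = 0.0032; adjusted p = 0.40 with an estimated correlation for both). The medians of the actin and adhesion (0.07, adjusted p = 0.025; adjusted p = 0.40 with an estimated correlation), glycolysis and hypoxia (-0.14, adjusted p = 0.024) and oxidative phosphorylation lists (-0.13, adjusted p = 0.012) were small, and the last 2 had an adjusted p = 0.40 with an estimated correlation. No gene was called with each line's own uninduced array as reference (1455 at an unadjusted p under 0.05) or with all probe sets tested (4376 probe sets at an unadjusted p under 0.05). Leaving out either K380R induced array left 1 call and leaving out any other array left 0.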

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

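The tests of compressed values and of transgene RNA below were chosen after the result was seen; the other was planned. Own induction changes that differed between lines were picked out by a test of the difference itself. Between the wild-type and tag-only lines 63 genes differed in this way, 61 with a higher change in the wild-type line and 2 with a lower one. The differences were 6.14 ± 0.33 (log2, SE; limma adjusted p = 0.017) for SAA1, 5.90 ± 0.23 for PRL, 5.54 ± 0.21 for RSPO3 and 4.95 ± 0.16 for DPP4 (adjusted p = 0.0069 each). Between the K380R and tag-only lines 4 genes differed, all higher with K380R, by 6.17 ± 0.33 for SAA1 (adjusted p = 0.026), 5.31 ± 0.23 for PRL, 4.51 ± 0.18 for PCGEM1, a long non-coding RNA gene, and 3.90 ± 0.16 for DPP4 (adjusted p = 0.012 each). Each of these rests on 1 uninduced and 2 induced arrays per line. In simulations with independent noise on each array, 10.5% and 10.96% of such calls were false. SAA1, PRL and RSPO3 lay on average below the arrays' medians in the uninduced and tag-only cells, and PCGEM1 did on the induced tag-only arrays. The sizes of their differences are therefore uncertain. For PRL the difference includes a tag-only change of -0.50 between dim levels, beside 5.41 in the wild-type line. Among probe sets without a gene name here, which the comparisons between groups left out, 840 were called between the wild-type and tag-only arrays, 589 higher and 251 lower. No group held the 4 arrays that a test for a single outlying array needs.

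Over genes chosen on the average change of both lines, the K380R line changed less than the wild-type line. Over the 194 genes whose changes averaged 1 or more over both lines, the mean change was 1.41 in the K380R line and 2.00 in the wild-type line, a ratio of 0.70, and 78.9% of the genes changed less with K380R. Over the 47 genes whose changes averaged -1 or less the means were -1.18 and -1.38, a ratio of 0.85, and 74.5% changed less with K380R. The share depended on the choice of genes. Of genes lowered by 1 or more, 93.1% changed less with K380R when chosen in the wild-type line but 28.3% when chosen in the K380R line. For raised genes the shares were 90.3% and 54.0%. The smaller change with K380R is thus less certain for lowered genes. Exchanged uninduced and 24 h arrays of the K380R line, as its source names have them, would put the array titled uninduced above the others over the 310 genes raised in the wild-type line. Its median there was 0.070 above the mean of the other uninduced arrays, against 0.78 for the array titled 24 h, which argues against the exchange. One common compression of the values on the K380R arrays would shrink all changes by 1 factor. Of the 241 genes whose changes averaged 1 or more in size, 13.7% lay more than 0.93 (3 SD of the difference between the lines over genes that hardly changed) off the common factor of 0.67, against 0.55% of the latter genes. This argues against compression as the whole cause. Less transgene RNA in the K380R line stays open, since the FLI1 probe set moved by only 0.082 in the wild-type line and whether it reads the transgene is not known here. An effect of the K380R change itself may account for the pattern too, but with 1 line per construct it cannot be told apart from a difference in transgene level.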

How the results depend on the processing

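Testing all probe sets, leaving out microRNA genes and choosing genes on other arrays were chosen after seeing the data; the other alternatives were planned. With each line's own uninduced array as reference, calls were 0 for tag-only against uninduced (136 in the main analysis), 63 for wild-type against tag-only (1658), 4 for K380R against tag-only (791), 0 for K380R against wild-type (144), 296 and 48 for the wild-type and K380R lines against uninduced (1661 and 544), 51 for induction (15) and 0 for time (2). This reference pairs the arrays by line. In simulations it recovered 82.1%, 77.6% and 74.6% of changes of 1 for the tag-only, wild-type and K380R lines against uninduced, but 8.96%, 8.96% and 7.46% for wild-type against tag-only, K380R against tag-only and K380R against wild-type. It recovered 100% of changes of 2 against uninduced and 93.9%, 89.4% and 92.4% between lines, so the cause of the losses is open. Of its simulated calls, on arrays with independent noise, 12.8% were false for wild-type against uninduced. The share was 10.5% and 10.96% for the wild-type and K380R lines against tag-only. At 24 h alone, limma called 0 genes in each of these comparisons except time, which was not run; at 48 h alone the counts were 0, 28, 0, 0, 39, 0 and 2. These fits use fewer arrays. With the source names' labels for the K380R line they were 0, 333, 0, 27, 62, 0, 0 and, for time, 0. Dropping dim genes kept 10949 genes and gave 214 calls for tag-only against uninduced, 254 for K380R against wild-type and 7 for time, and the trended robust variance model gave 275, 312 and 4; the cause was not tested. Testing all probe sets gave 0, 15, 2 and 0 for tag-only against uninduced, K380R against wild-type, induction and time. An added 2-fold threshold left 36, 429, 253, 73, 372 and 171 genes in the 6 comparisons between groups. Leaving out 1 array at a time gave 0 to 29 calls for tag-only against uninduced, 444 to 1476 for wild-type against tag-only, 103 to 710 for K380R against tag-only, 6 to 145 for K380R against wild-type, 434 to 1464 and 51 to 400 for the wild-type and K380R lines against uninduced, 1 to 19 for induction and 0 to 1 for time; an arm left with 1 array was taken to vary like the others. The slope of the wild-type line (0.17) was 1.13 over the 1 gene changed by 2 or more, 0.26 over the fixed target lists, 0.38 with the mean of the uninduced arrays as reference and 0.12 (a ratio of mean changes) with genes chosen on other arrays, and 0.050 to 0.18 with 1 array left out. That of the K380R line (0.19) was 1.12, 0.45 and 0.33, and 0.085 to 0.21 with 1 array left out. It turned to -0.073 with the source names' labels, which the values given above for the K380R arrays argue against. The cause of these shifts in slope was not tested. Dropping the time term, means over probe sets and cyclic loess kept each count between groups within 1.5 times. Of 120 list tests, 44 were called at the preset correlation, of which 1 (fusion-activated genes in tag-only against uninduced) held with an estimated correlation, 17 with fry and 28 with the own-line reference. Of 4618 checks of 257 named-gene results, 2740 kept their direction and call, 1878 kept the direction but lost the call, and 0 changed direction. All of these results had been called on the same arrays. A kept direction was therefore likely from the start and is no independent check. The named results kept their call in 51 cases with the own-line reference, 33 with the source names' labels, 17 at 48 h alone and 0 at 24 h alone. Background signal was not used here, so dimness was judged against each array's median.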

Other observations

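The tests of fusion activity, of EWSR1 and of the splits within lines below were chosen after the result was seen; the test over all splits was planned. The per-array level of replication genes on induction was lowest in the wild-type line. The median level of the 22 G1/S replication genes, relative to the mean of the uninduced arrays, was -0.14 and -0.24 at 24 h and 48 h in the tag-only line, -0.37 and -0.44 in the K380R line and -0.56 and -0.81 in the wild-type line, against -0.03 to 0.04 on the uninduced arrays. Cholesterol synthesis genes lay at -0.42 and -0.18 in the tag-only line, -0.32 and -0.25 in the K380R line and -0.46 and -0.65 in the wild-type line. Single conditions have 1 array, so the order of these values has no replicate check.

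Among the 20 genes lowered at least 2-fold in the tag-only line, 6 lay 0.5 or more above their own uninduced level in both re-expressing lines, a choice made after their values were seen. PCGEM1 stood at -1.86 in the tag-only line, 2.53 in the wild-type line and 2.66 in the K380R line, and KMO at -1.10, 3.42 and 2.71. ENPEP, which encodes an aminopeptidase, stood at -1.01, 2.15 and 1.47, IGF1 at -1.28, 0.97 and 1.95, FEZF1-AS1 at -1.58, 1.49 and 0.56, and CLUL1 at -1.48, 1.02 and 0.63.

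In contrast, 15 genes, among them CXCR4, C7, TSPAN8, RET and SPP1, were called on induction over the 3 constructs together. Of the 84 splits of the 9 arrays into 3 and 6, 2 called at least as many genes, the real one with 15 and another with 228. The other split set both wild-type induced arrays and the K380R 48 h array apart, which points to a structure of the arrays by construct. The arrays are thus not freely exchangeable, and the count over all 84 splits does not exclude chance. Of the 27 splits that set 1 array of each line apart, as the design does, only the real one called as many. It called 15 genes against 0 at most in the others, and 51 against 0 with the line as a block. Every other such split puts induced and uninduced arrays together in at least 1 group. The changes on re-expression then raise the spread and make calls unlikely from the start. These splits therefore do not exclude chance either. A uniformly low fusion activity in both re-expressing lines is argued against by the 6 genes above that overshot their starting level there. The known fusion-activated genes were lower as a list over all induced arrays (median -0.08, camera adjusted p = 0.0073, or 0.25 with an estimated correlation). This pooled fall came mainly from the tag-only arrays, which carry no re-expressed fusion. Relative to the mean of the uninduced arrays, the list's median was -0.40 and -0.45 at 24 h and 48 h in the tag-only line. It was -0.14 and -0.02 in the wild-type line and 0.10 and 0.04 in the K380R line. The pooled value thus does not show low activity in the re-expressing lines. Low activity at part of the targets there stays open. Loss of 0.5 or more of EWSR1 transcript through the shared 5′ untranslated region is argued against in the tag-only line only. In the wild-type and K380R lines the EWSR1 probe set may also read the transgene, which could mask such a loss, so it cannot decide there. EWSR1 differed from uninduced by -0.12 ± 0.09 (SE) in the tag-only line and by 0.14 ± 0.09 in each of the wild-type and K380R lines, and the own changes were -0.13, 0.04 and 0.25. A smaller loss in the tag-only line was not excluded. An effect of doxycycline or of the hairpin itself stays open and was not tested.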
